A study of Drosophila melanogaster with 12 samples.

How the data were processed

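The analysis used the processed tables that the authors deposited. The gene table held 17469 genes in 12 columns, in RPM, reads scaled to the library size, per the file headers. The transposon table of the Daed knockdown held read counts, RPM and mean piRNA length in nucleotides for 130 elements, as 1 merged value per group, per the file headers. Read counts of the gene table were recovered from the deposited RPM. Of the gene values 100% came back to whole reads within 0.01. STAR, HTSeq, BDGP6 and dm6 are named in the submitters' processing notes, without versions. Symbols and dm6 coordinates came from the RefSeq gene table, and 17340 of 17469 gene identifiers (99.3%) had a symbol.

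The main test, thresholds, gene lists and alternatives were fixed before the data were examined. The plan had assumed counts. As the gene table held RPM, the fallback fixed beside it was used, limma-trend on log2(RPM + 1) with all 12 libraries in 1 fit. Genes needed at least 1 RPM in at least 3 libraries, which left 8246. P values were adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05, and again over the members of each list alone. Camera was run with a preset correlation of 0.01 on log2(RPM + 1) in place of the planned log2 CPM with a prior count of 2, which served as an alternative. With it 1 list passed with deltaSAM and 12 with KEE. Lists needed at least 5 tested members. The microRNA list matched no gene of the table, and the 37 mitochondrially encoded genes had no reads, so neither was tested.

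Named genes were the 12 largest rises and 12 largest falls by log2 fold change with an adjusted p under 0.05, no overlap of the libraries between groups and a mean of at least 20 RPM in the higher group. The genes armi, daed, flam, tj, piwi and zuc were named whatever the result, as were up to 4 members of each list by p. For the difference between experiments the 5 most significant genes in each direction were named. Shares of gene reads were compared by exact permutation of 3 against 3 libraries. Transposon ratios carry an exact conditional interval on the deposited read counts, and the 10 largest and 10 smallest ratios among elements of at least 20 RPM in the higher group were named. The plan had no size rule for merged values. The 1.5-fold rule was added after the values had been seen.

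In a test with planted changes, reads were simulated from the mean levels and library totals in 10 repeats, with known changes of 1.5, 2 or 4-fold. In the Daed comparison 17.3%, 52.4% and 84.2% of these were recovered, and in the Armi comparison 13.4%, 49.1% and 86.5%. False calls were 13.0% and 1.00% of all calls. In the Daed comparison 6.69% of the calls on genes of at least 10 RPM were false. The simulated groups shared their means apart from a small set of planted changes, balanced up and down, with a common dispersion. The data held far more changes and a shift in the part of the library assigned to genes. These false shares therefore need not hold for the real calls.

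Alternatives covered pseudocounts of 0.1 and 10, no filter, at least 10 RPM, a replicate block, removal of structural RNA genes, gene-table totals, centring on the median gene, the libraries of 1 experiment alone, edgeR with several factors and DESeq2 on recovered reads, each library left out in turn, and replicate 3 of the deltaSAM group and of the WT group of the Armi knockdown left out. For lists they covered an estimated correlation and fry. Scaling to the gene-table total, centring, edgeR with TMM factors and leaving out replicate 3 of the deltaSAM group and of the WT group of the Armi knockdown were added after the data had been seen. The fit of all 12 libraries was kept as fixed in the plan, although the planted changes gave fewer false calls in the Daed comparison with other fits. The transposon comparison of the Armi knockdown was not analysed here. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.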

Results

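The data describe small RNAs bound to Piwi in the ovarian somatic cell line of Drosophila. PIWI-interacting RNAs (piRNAs) in these cells come from transposon-rich loci such as flam and from the messenger RNAs of genes such as tj. Per the labels, endogenous Daedalus (Daed) or Armitage (Armi) was knocked down with siRNA and replaced from a plasmid. The Daed knockdown carried wild-type Daed (WT) or Daed lacking its SAM domain (deltaSAM). The Armi knockdown carried wild-type Armi (WT) or the variant labelled KEE, whose meaning was not looked up. Each of the 4 groups held 3 libraries, and no library of an un-rescued knockdown was part of the 12.

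The Daed libraries held 1961721, 1812139 and 1396369 reads for WT and 1701393, 1836515 and 1810948 for deltaSAM. The Armi libraries held 3828687, 2335292 and 2654833 reads for WT and 3766284, 3697324 and 3995009 for KEE. Nothing states that the replicates were separate cultures, so every p below measures only the spread between these samples. The first principal component of the 8246 tested genes held 46.0% of the variance and set KEE apart from the other 3 groups. The second held 17.4% and set deltaSAM apart from WT in the Daed knockdown.

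Reads assigned to genes took a larger part of the library with either variant. In the Daed knockdown this part was 50.2 ± 0.813% (SD, n = 3) with WT and 58.0 ± 0.598% with deltaSAM. In the Armi knockdown it was 63.4 ± 1.32% with WT and 79.5 ± 0.251% with KEE. The groups did not overlap in either experiment, and the exact permutation p was 0.1 in each, the smallest that 3 against 3 libraries allow. The genes that together held 50% of the gene reads numbered 184 with WT and 162 with deltaSAM, and 194 with WT and 251 with KEE.

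**Figure D1:**
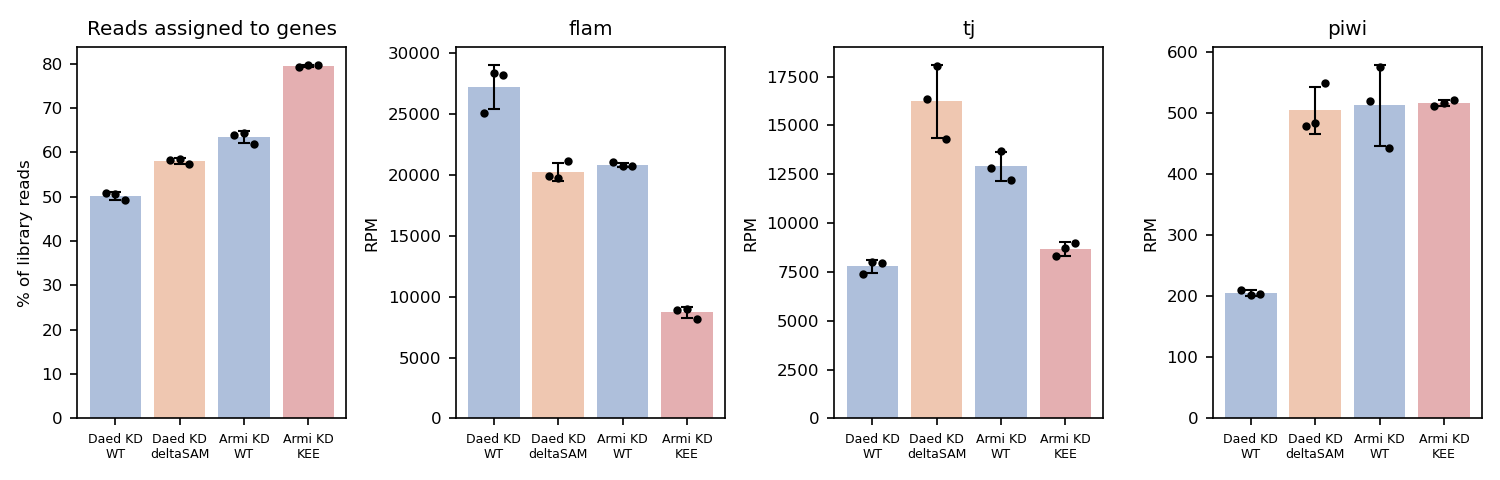
Part of the library assigned to genes, and levels of flam, tj and piwi piRNAs in RPM, for the 4 groups. Points are libraries, bars are means and lines are SD over 3 libraries.

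The flam locus (dm6 X:21631891-21790731), the main piRNA cluster of the ovarian soma, held a smaller part of the library with either variant. RPM and shares are relative, so an absolute loss of flam piRNAs was not tested. With deltaSAM flam fell from 27237 ± 1841 to 20269 ± 742 RPM (SD, n = 3), a log2 fold change of -0.42 ± 0.07 (SE). With KEE it fell from 20852 ± 175 to 8702 ± 440 RPM, a log2 fold change of -1.26 ± 0.07. The adjusted p was 2.3e-05 with deltaSAM and 6.2e-15 with KEE (limma with Benjamini-Hochberg). As a share of all gene reads, flam went from 5.43 ± 0.423% to 3.49 ± 0.165% with deltaSAM and from 3.29 ± 0.0655% to 1.09 ± 0.0576% with KEE (permutation p = 0.1 each).

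The messenger RNA of tj (2L:19464267-19467758), the best known genic piRNA source of these cells, moved in opposite directions. With deltaSAM tj piRNAs rose from 7791 ± 339 to 16229 ± 1885 RPM (1.05 ± 0.08). With KEE they fell from 12911 ± 730 to 8669 ± 356 RPM (-0.57 ± 0.08). The tj share of gene reads went from 1.55 ± 0.0837% to 2.79 ± 0.299% with deltaSAM and from 2.04 ± 0.0807% to 1.09 ± 0.0414% with KEE. The adjusted p for tj was 1.8e-11 and 4.3e-07 (limma with Benjamini-Hochberg). The 10 most abundant genes, namely flam, tj, Myc, l(2)gl, brat, crol, CycG, msk, CG6700 and CG11360, held 14.2 ± 0.239% of gene reads with WT and 14.8 ± 0.203% with deltaSAM. In the Armi knockdown they held 12.2 ± 0.306% with WT and 6.46 ± 0.0849% with KEE.

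The piRNAs of piwi itself rose with deltaSAM from 205.1 ± 4.79 to 505 ± 39.1 RPM (1.29 ± 0.09, adjusted p = 3.6e-12, limma with Benjamini-Hochberg). With KEE piwi went from 513 ± 66.6 to 517 ± 4.602 RPM (0.02 ± 0.09, adjusted p = 0.883). Scaled to the gene-table total or centred on the median gene, piwi fell with KEE (-0.31 and -0.33). The armi gene fell with deltaSAM from 289 ± 21.5 to 184 ± 20.4 RPM (-0.65 ± 0.08, adjusted p = 5.5e-07). It rose with KEE from 878 ± 30.3 to 1553 ± 26.8 RPM (0.82 ± 0.08, adjusted p = 2.3e-09). The daed gene gave 30.4 ± 2.46 to 30.3 ± 1.79 RPM in the Daed knockdown (adjusted p = 0.997) and 3.45 ± 1.11 to 5.67 ± 1.29 RPM in the Armi knockdown (0.60 ± 0.22, adjusted p = 0.0301). The nuclease gene zuc rose with deltaSAM from 1.25 ± 0.830 to 3.33 ± 1.57 RPM (0.94 ± 0.37, adjusted p = 0.0452) and gave 3.79 ± 1.17 to 3.87 ± 0.980 RPM in the Armi knockdown (adjusted p = 0.954). The calls on zuc with deltaSAM and daed with KEE were lost in 9 and 13 of the alternative analyses. Reads from the rescue plasmids could not be told from endogenous armi or daed reads.

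In the deltaSAM rescue piRNAs of Clc, the clathrin light chain, rose from 54.6 ± 5.81 to 327 ± 39.2 RPM (SD, n = 3; log2 fold change 2.56 ± 0.11, SE). The uncharacterised CG11141 rose from 303 ± 22.3 to 1497 ± 223 RPM (2.29 ± 0.09). The myosin regulatory light chain gene sqh rose from 205.2 ± 8.31 to 812 ± 141 RPM (1.96 ± 0.10), and mmy, which makes UDP-N-acetylglucosamine, from 37.1 to 160 RPM (2.08 ± 0.14). The glycolytic gene Pgi rose from 44.0 to 164 RPM (1.88 ± 0.13) and the helicase gene Pif1 from 21.5 to 108 RPM (2.24 ± 0.17). Rises from lower levels came at Cda5 (4.06 to 26.0 RPM), CG4627 (3.92 to 20.2 RPM), Elk (6.18 to 31.0 RPM), Flo1 (7.45 to 32.5 RPM), aph-1 (6.03 to 27.6 RPM) and PrBP (9.40 to 40.1 RPM).

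The largest fall with deltaSAM was at the uncharacterised CG13685, from 47.3 ± 3.98 to 2.61 ± 1.10 RPM (-3.78 ± 0.25). The nuclear envelope gene fs(1)Ya fell from 119 ± 5.23 to 21.2 ± 3.09 RPM (-2.44 ± 0.15), and the SUMO protease gene velo from 81.4 ± 1.81 to 17.8 ± 1.70 RPM (-2.14 ± 0.13). CG3635 fell from 211 to 48.3 RPM (-2.10 ± 0.13), CG8701 from 90.2 to 19.9 RPM (-2.16 ± 0.21) and CG11635 from 102 to 26.8 RPM (-1.92 ± 0.18). The noncoding asRNA:CR42871 fell from 182 to 46.6 RPM, lncRNA:CR44564 from 44.9 to 11.2 RPM, lncRNA:CR44779 from 20.8 to 4.66 RPM and lncRNA:CR44731 from 22.0 to 5.601 RPM. CG42674 fell from 41.7 to 10.7 RPM and CG14221 from 22.8 to 5.27 RPM.

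In total 2987 of 8246 genes changed with deltaSAM at an adjusted p under 0.05, 1429 up and 1558 down (limma with Benjamini-Hochberg). Of these, 1053 had an absolute log2 fold change of at least 1, 364 up and 689 down. Rises made up 47.8% of the changed genes, against 28.9% when scaled to the gene-table total, 68.8% when each library was centred on its median gene and 57.4% with edgeR and TMM factors. In the planted-change test 13.0% of the calls of this fit were false in this comparison, against 3.06% when only the 6 Daed libraries were fitted and 4.38% with edgeR and TMM factors. Those analyses called 2437 (1221 up, 1216 down) and 2474 genes (1419 up, 1055 down).

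With KEE piRNAs of the transcription factor gene zfh1 rose from 508 ± 31.1 to 3359 ± 58.7 RPM (SD, n = 3; log2 fold change 2.73 ± 0.09, SE). The calmodulin gene Cam rose from 112 ± 11.2 to 973 ± 58.4 RPM (3.11 ± 0.11), FBXO11 from 85.2 ± 14.3 to 694 ± 21.5 RPM (3.03 ± 0.11) and HIP-R from 15.8 ± 1.20 to 154 ± 1.20 RPM (3.21 ± 0.16). The Wnt receptor gene fz2 rose from 68.2 to 487 RPM (2.82 ± 0.11), the co-chaperone gene Stip1 from 52.5 to 362 RPM (2.76 ± 0.12) and the actin regulator gene ena from 18.2 to 163 RPM (3.09 ± 0.19). Rises also came at lolal (87.2 to 585 RPM), eIF5 (11.4 to 81.5 RPM), CG8675 (9.79 to 82.5 RPM), CG10055 (12.7 to 96.6 RPM) and qkr58E-1 (5.58 to 50.5 RPM).

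Tif-IA, a factor of RNA polymerase I transcription, fell with KEE from 976 ± 34.4 to 202 ± 7.23 RPM (-2.27 ± 0.08). The largest fall was at lectin-37Da, from 106 ± 18.7 to 12.5 ± 2.41 RPM (-2.98 ± 0.14). The amino acid transporter gene slif fell from 102 to 18.7 RPM (-2.39 ± 0.13) and the sulfonylurea receptor gene Sur from 133 to 29.0 RPM (-2.16 ± 0.12). CG13685, also the largest fall with deltaSAM, went from 25.1 to 3.596 RPM (-2.55 ± 0.25). CG10588 fell from 29.6 to 3.88 RPM, CG7309 from 31.5 to 4.72 RPM and CG43844 from 88.9 to 19.0 RPM. The noncoding asRNA:CR42871 fell from 110 to 22.8 RPM, asRNA:CR45137 from 81.1 to 15.6 RPM, lncRNA:CR44564 from 51.5 to 9.96 RPM and lncRNA:CR45399 from 32.6 to 3.66 RPM.

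In total 3684 of 8246 genes changed with KEE, 2720 up and 964 down (limma with Benjamini-Hochberg). At an absolute log2 fold change of at least 1 there were 1865, 1482 up and 383 down. Rises made up 73.8% of the changed genes, against 55% when scaled to the gene-table total, 49.7% when centred on the median gene and 49.0% with edgeR and TMM factors. The excess of rises thus depended on the scaling, and none was left when centred on the median gene or with TMM factors. In the planted-change test 1.00% of the calls of this fit were false in this comparison. The value was 4.11% with only the 6 Armi libraries fitted and 3.36% with edgeR and TMM factors. That test held no shift in the part of the library assigned to genes, so it cannot show false rises from the scaling.

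**Figure D2:**
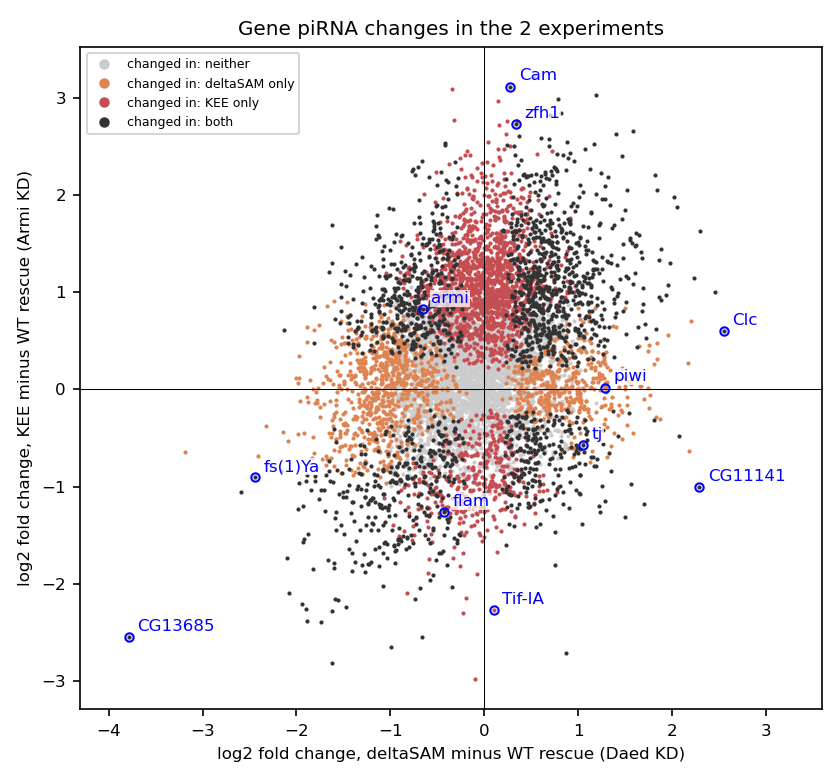
Log2 fold changes of the 8246 tested genes with deltaSAM (horizontal) and with KEE (vertical), each against its WT rescue, n = 3 libraries per group. Colours mark genes with an adjusted p under 0.05, and circles mark named genes.

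The changes of the 2 experiments overlapped in part. Genes such as hh and eya rose in both, hh from 153 to 473 RPM with deltaSAM and from 147 to 410 RPM with KEE, and eya from 36.2 to 69.6 RPM and from 28.9 to 81.0 RPM. Genes such as pgc and Dcr-2 fell in both, pgc from 354 to 201 RPM and from 296 to 103 RPM, and Dcr-2 from 943 to 512 RPM and from 950 to 493 RPM. Both rose for 757 genes (471 expected from independent calls) and both fell for 347 (182 expected). Opposite calls came for 240 genes that rose with deltaSAM and fell with KEE (167 expected) and for 439 that fell and rose (514 expected). The expected counts treat all genes alike, but calls gathered in abundant genes. In the highest of 10 equal bins of genes by mean RPM, 427 of 825 rose with deltaSAM and 434 with KEE. In the lowest bin 16 of 825 rose with each. Abundance alone can thus move these counts away from those expected, and its part was not tested. Across genes the log2 fold changes had a Pearson r of 0.24 and a Spearman rho of 0.21.

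The effect of KEE exceeded that of deltaSAM most clearly at CNBP (difference in log2 fold change 2.98 ± 0.10, SE), spen (3.03 ± 0.12), rin (3.01 ± 0.13), CG14441 (2.77 ± 0.13) and Bicra (2.40 ± 0.10). It lay below most clearly at CG11141 (-3.30 ± 0.13), Tif-IA (-2.37 ± 0.11), CG13384 (-2.49 ± 0.13), ArfGAP1 (-2.43 ± 0.14) and Uhg3 (-1.97 ± 0.11). The difference was 1.47 ± 0.12 for armi, -0.84 ± 0.10 for flam, -1.63 ± 0.11 for tj and -1.27 ± 0.13 for piwi. The adjusted p was 4.9e-11, 7.2e-08, 1.7e-12 and 2.0e-09 (limma with Benjamini-Hochberg). It was 0.135 for daed and 0.169 for zuc. In total 3334 genes differed, 2428 higher and 906 lower with KEE. The higher part was 72.8%, against 67.1% scaled to the gene-table total, 38.8% centred on the median gene and 44.6% with edgeR and TMM factors.

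The median change varied with the abundance of the gene. With deltaSAM the median log2 fold change was -0.21 in the lowest of 10 equal bins of genes by mean RPM, -0.30 in bin 3 and 0.26 in the highest. With KEE it was -0.07 in the lowest bin, 0.56 in bin 8 and 0.30 in the highest. Over all tested genes the median was -0.10 with deltaSAM and 0.30 with KEE.

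**Figure D3:**
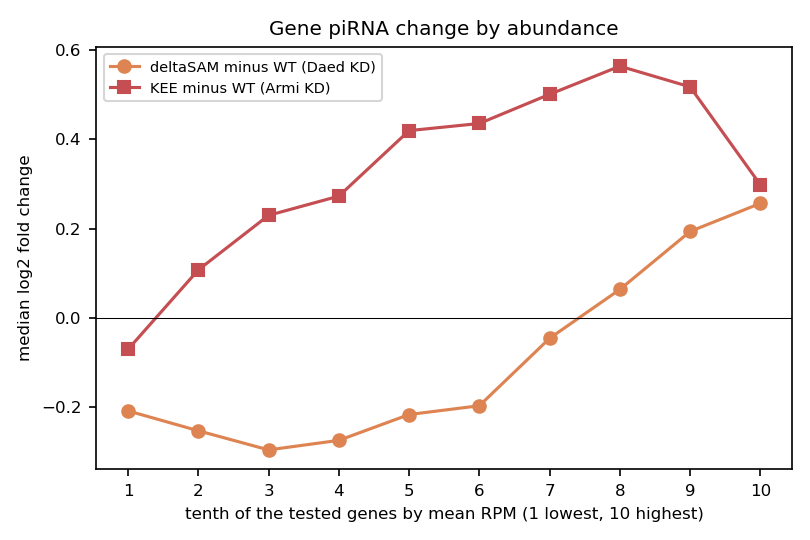
Median log2 fold change of genes in 10 equal bins of mean RPM over the 12 libraries, with deltaSAM and with KEE against the WT rescue of the same knockdown. Bin 1 is the lowest.

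Of the genes of oxidative phosphorylation encoded in the nucleus, more fell than rose with deltaSAM. COX7C fell from 55.9 ± 4.18 to 19.6 ± 3.42 RPM (SD, n = 3; -1.48 ± 0.15), UQCR-C2 from 21.1 to 7.64 RPM and ND-MWFE from 10.5 to 3.18 RPM, while Cyt-c-p rose from 55.7 to 119 RPM (1.07 ± 0.13). Of 66 tested members 4 rose and 24 fell, or 4 and 27 when adjusted over the list alone. The list passed camera at an adjusted p of 0.0187 (Benjamini-Hochberg over the lists, preset correlation), with adjusted p = 0.124 with an estimated correlation. With the 31 members of at least 10 RPM the adjusted p was 0.229. The falls were 33 of 70 tested members scaled to the gene-table total and 20 of 66 centred on the median gene. With TMM factors they were 16 of 50.

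In the same fit no other list passed with deltaSAM. Among mitochondrial ribosomal proteins 0 of 67 rose and 10 fell (0 and 8 over the list alone, camera adjusted p = 0.0588). Of these mRpL23 went down from 19.7 to 6.19 RPM, and 16 of 71 fell at the gene-table total. Only 9 members had at least 10 RPM. Among all genes 28 of 824 rose and 123 fell in bin 3 by mean RPM, and 48 of 824 rose and 183 fell in bin 5. The falls in this list thus lay near the share of other low genes. Among cytosolic ribosomal proteins 12 of 83 rose and 27 fell (13 and 27; 0.317), with RpL4 down from 168 to 54.7 RPM and RpL11 up from 131 to 302 RPM. The ribosomal protein counts depended on the scaling, with 8 up and 39 down at the gene-table total, 20 and 15 centred on the median gene and 15 and 23 of 80 with TMM factors. In glycolysis 5 of 12 rose and 1 fell (5 and 1; 0.116), with Eno up from 336 to 624 RPM. In Hedgehog, Wnt and JAK-STAT signalling 8 of 15 rose and 4 fell (8 and 4; 0.170), with fu up from 19.6 to 46.1 RPM and ci down from 322 to 206 RPM. Among structural and transfer RNAs 25 of 142 rose and 11 fell (17 and 7; 0.170, adjusted p = 0.807 with an estimated correlation), with tRNA:Tyr-GTA-1-4 up from 1.37 to 10.0 RPM and snoRNA:Or-aca4 down from 72.5 to 21.9 RPM. The camera value for structural RNAs was 0.00270 at the gene-table total and 0.997 without replicate 3 of deltaSAM and of WT in the Armi knockdown.

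The piRNA biogenesis factors of the soma split with deltaSAM. Here 7 of 15 rose and 4 fell (7 and 4 over the list alone; camera adjusted p = 0.502), with SoYb down from 69.5 to 38.3 RPM and Nbr up from 43.3 to 77.8 RPM. Of the Piwi nuclear silencing factors 3 of 15 rose and 2 fell (3 and 2; 0.826). The SUMO ligase gene Su(var)2-10 fell from 2115 ± 220 to 1125 ± 35.5 RPM (-0.91 ± 0.08) and mael rose from 14.1 to 23.95 RPM. In small RNA machinery outside the piRNA pathway 3 of 11 rose and 5 fell (3 and 5; 0.826), with r2d2 up from 59.2 to 112 RPM. Among germline markers 3 of 18 rose and 2 fell (2 and 2; 0.692), with ovo up from 21.8 to 36.7 RPM. Among follicle cell genes 5 of 13 rose and 4 fell (5 and 5; 0.808), with mirr up from 263 ± 5.87 to 696 ± 66.9 RPM (1.40 ± 0.09). Among translation factors 6 of 44 rose and 9 fell (6 and 9; 0.945), with eIF2A up from 136 to 448 RPM and eIF4H1 down from 370 to 178 RPM. Among heat shock and chaperone genes 3 of 11 rose and 4 fell (4 and 4; 0.945), with Hsp60A down from 67.0 to 24.6 RPM and Hsc70-3 up from 510 to 847 RPM.

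In the cytoskeleton list with deltaSAM 5 of 21 rose and 8 fell (5 and 9 over the list alone; camera adjusted p = 0.826), with Arp3 up from 522 to 965 RPM and beta-Spec down from 40.8 to 14.4 RPM. In adhesion and extracellular matrix 5 of 20 rose and 5 fell (5 and 5; 0.826), with mys up from 189 to 324 RPM and LanA down from 261 to 147 RPM. In the cell cycle 5 of 27 rose and 8 fell (5 and 9; 0.953), with Cdk4 up from 60.6 to 168 RPM. In the JNK pathway 0 of 12 rose and 2 fell (0 and 2; 0.692), namely Ets21C from 17.57 to 6.21 RPM and Atf3 from 114 to 85.3 RPM. In mRNA decay 6 of 17 rose and 1 fell (6 and 1; 0.317), with Smg6 up from 174 to 433 RPM. In the mitochondrial outer membrane 3 of 13 rose and 3 fell (4 and 3; 0.945), with porin down from 130 to 91.2 RPM. In innate immunity 2 of 6 rose and 0 fell (2 and 1; 0.826), namely cact and dl. Blood cell markers gave 1 rise (crq) and 2 falls (ush and Pxn) of 5 (1 and 2; 0.931), neuron markers 1 rise (elav) and 2 falls (futsch and VAChT) of 7 (1 and 2; 0.826), and muscle markers 1 rise (sls) of 5 (1 and 0; 0.826). Which direction held more calls turned with the scaling in further lists. Centred on the median gene, 12 translation factors rose and 5 fell, 8 cell cycle genes rose and 3 fell, 7 cytoskeleton genes rose and 4 fell, and 4 chaperone genes rose and 2 fell. The adhesion list had 3 rises and 7 falls at the gene-table total and 8 and 2 centred. The JNK pathway kept its direction, with 0 rises at either scaling, but had 6 falls at the gene-table total and 1 centred. At the gene-table total 2 outer membrane genes rose and 5 fell, 2 mRNA decay genes rose and 4 fell, 4 follicle cell genes rose and 5 fell, 1 Piwi nuclear silencing gene rose and 2 fell, and 1 germline marker rose and 2 fell. The histone list had 1 tested gene, His2B:CG33868, with an adjusted p of 0.0525.

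**Figure D4:**
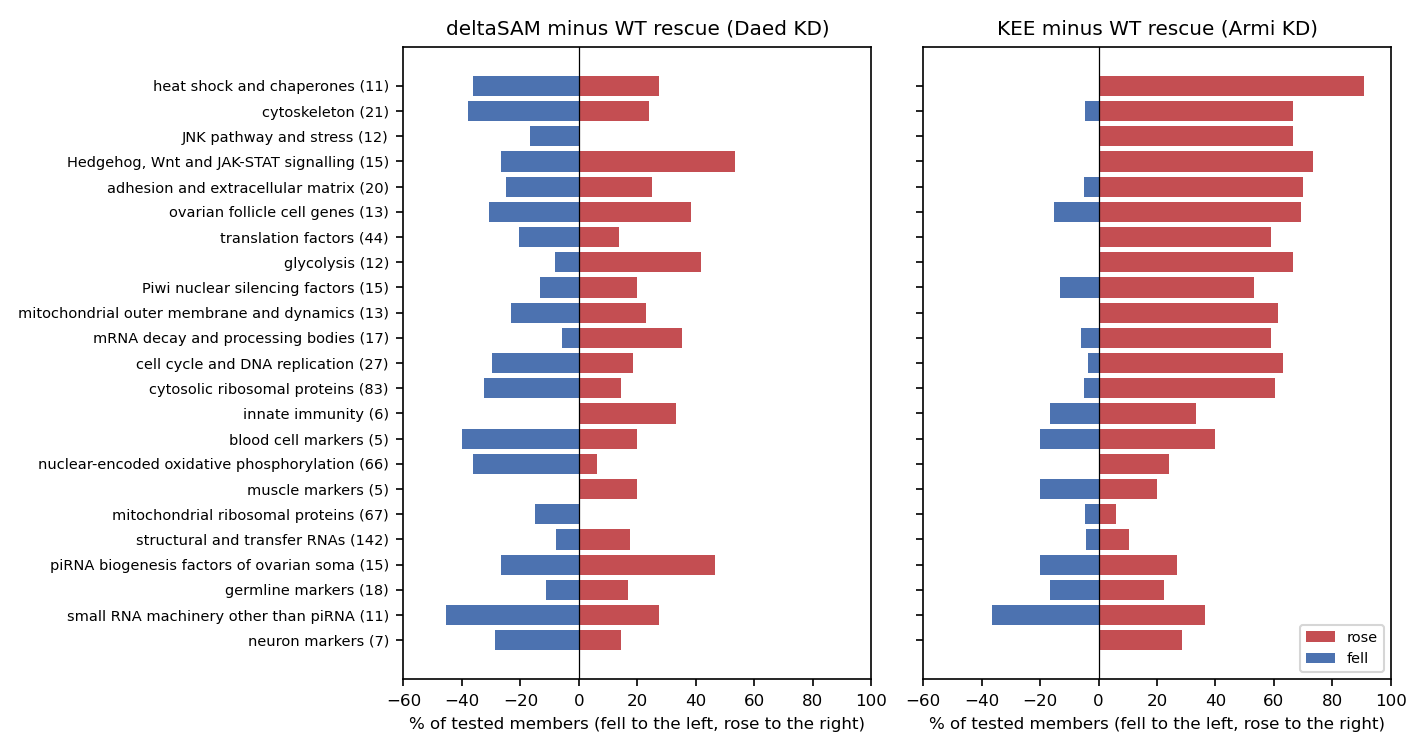
Percent of tested members that rose (right) or fell (left) in each gene list, with deltaSAM and with KEE against the WT rescue of the same knockdown. Numbers in brackets are tested members.

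Chaperone and translation factor genes were among those that rose with KEE. The endoplasmic reticulum chaperone gene Hsc70-3 rose from 736 ± 29.9 to 3390 ± 48.7 RPM (SD, n = 3; 2.20 ± 0.09), stv from 35.7 to 159 RPM, Hsc70-4 from 242 to 615 RPM and Hsp83 from 863 ± 47.5 to 2126 ± 19.0 RPM (1.30 ± 0.11). Of heat shock and chaperone genes 10 of 11 rose and 0 fell, the same over the list alone. The elongation factor gene eEF1alpha1 rose from 489 ± 23.1 to 1290 ± 38.4 RPM (1.40 ± 0.08), eIF1 from 71.8 to 226 RPM and eEF5 from 108 to 267 RPM. Of translation factors 26 of 44 rose and 0 fell, the same over the list alone. In Hedgehog, Wnt and JAK-STAT signalling 11 of 15 rose and 0 fell, also over the list alone, with fz up from 222 to 464 RPM and cos from 93.1 to 188 RPM. These 3 lists passed camera at 0.00227, 0.00121 and 0.00222 (Benjamini-Hochberg over the lists), and each gave adjusted p = 0.0452 with an estimated correlation. At 10 RPM or more all 3 calls were lost (0.0600, 0.0536 and 0.0600). At the gene-table total 7 of 11 chaperones rose and 0 fell, and 22 of 46 translation factors rose and 2 fell. Centred on the median gene, 7 chaperones rose and 0 fell, and 22 of 44 translation factors rose and 4 fell. The share of rises with KEE also varied with abundance. Among all genes 488 of 825 rose in bin 8 and 485 of 824 in bin 9 of the 10 bins by mean RPM. The 26 of 44 translation factors lay near that share. So did 50 of 83 cytosolic ribosomal protein genes, 17 of 27 cell cycle genes, 10 of 17 mRNA decay genes and 8 of 13 mitochondrial outer membrane genes. Such counts do not by themselves set these lists apart from other abundant genes.

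Further lists passed camera with KEE only at the preset correlation. The actin gene Act5C rose from 211 ± 18.5 to 998 ± 50.3 RPM (2.24 ± 0.10) and chic from 209 to 893 RPM, in a cytoskeleton list with 14 of 21 up and 1 down (15 and 1 over the list alone; 0.00217, adjusted p = 0.0668 with an estimated correlation). The JNK target puc rose from 55.7 to 225 RPM and Atf3 from 178 to 662 RPM, with 8 of 12 up and 0 down (10 and 0; 0.00567, adjusted p = 0.0534 with an estimated correlation). RpL11 rose from 146 to 589 RPM and RpL24 from 70.7 to 307 RPM, with 50 of 83 cytosolic ribosomal protein genes up and 4 down (51 and 5; 0.0154, adjusted p = 0.263 with an estimated correlation). Their counts were 22 up and 6 down at the gene-table total (camera adjusted p = 0.124), 22 and 8 centred on the median gene, and 18 and 17 of 80 with TMM factors. The poly(A)-binding protein gene pAbp rose from 573 ± 55.7 to 3270 ± 190 RPM (2.51 ± 0.09) and Edc3 from 138 to 462 RPM, with 10 of 17 mRNA decay genes up and 1 down (10 and 1; 0.0216, adjusted p = 0.0686 with an estimated correlation). The matrix gene trol rose from 267 to 611 RPM and LanB2 from 100 to 286 RPM, with 14 of 20 adhesion genes up and 1 down (14 and 1; 0.0246, adjusted p = 0.0686 with an estimated correlation).

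The enolase gene Eno rose with KEE from 273 ± 8.89 to 1420 ± 94.6 RPM (2.37 ± 0.08) and Ldh from 20.6 to 94.3 RPM, with 8 of 12 glycolysis genes up and 0 down (8 and 0; 0.0416, adjusted p = 0.259 with an estimated correlation). porin rose from 87.6 to 267 RPM and Tom40 from 68.4 to 177 RPM, with 8 of 13 mitochondrial outer membrane genes up and 0 down (9 and 0; 0.0416, adjusted p = 0.268 with an estimated correlation). chinmo rose from 1439 ± 52.0 to 4449 ± 217 RPM (1.63 ± 0.07) and br from 155 to 462 RPM, with 9 of 13 follicle cell genes up and 2 down (9 and 2; 0.0416, adjusted p = 0.107 with an estimated correlation). E2f1 rose from 92.6 to 375 RPM and stg from 109 to 239 RPM, with 17 of 27 cell cycle genes up and 1 down (17 and 1; 0.0495, adjusted p = 0.197 with an estimated correlation). The cell cycle counts were 10 up and 3 down at the gene-table total and centred on the median gene, and 10 and 5 of 24 with TMM factors. At the gene-table total 5 glycolysis, 5 outer membrane and 5 JNK pathway genes rose. Structural and transfer RNAs ranked lower than other genes (0.0496, adjusted p = 0.466 with an estimated correlation), though 15 of 142 rose and 6 fell (11 and 3), with snRNA:U7 up from 5.78 to 30.3 RPM. At the gene-table total the calls on cell cycle, follicle cell and structural RNA genes were lost (0.0932, 0.0932 and 0.433), and 6 structural RNA genes rose and 8 fell. Without replicate 3 of deltaSAM and of WT in the Armi knockdown the same calls were lost (0.0703, 0.0744 and 0.230). With genes of at least 10 RPM no list passed in either comparison.

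The other lists did not pass with KEE. In oxidative phosphorylation 16 of 66 rose and 0 fell (14 and 0 over the list alone; camera adjusted p = 0.897), with ATPsynC up from 335 ± 36.2 to 1035 ± 67.6 RPM (1.63 ± 0.09). The counts for oxidative phosphorylation were 13 up and 6 down of 70 at the gene-table total, 13 and 10 centred on the median gene, and 11 and 13 of 50 with TMM factors. Of mitochondrial ribosomal proteins 4 of 67 rose and 3 fell (3 and 1; 0.273), with mRpL36 up from 9.34 to 23.97 RPM. Of piRNA biogenesis factors 4 of 15 rose and 3 fell (4 and 3; 0.359), with the Yb body gene fs(1)Yb down from 89.1 ± 1.53 to 34.2 ± 3.62 RPM (-1.36 ± 0.12) and BicD from 268 to 195 RPM. Of Piwi nuclear silencing factors 8 of 15 rose and 2 fell (8 and 2; 0.101), or 5 and 2 at the gene-table total, with ctp, a dynein light chain gene, up from 118 to 251 RPM and Su(var)2-10 down from 1741 ± 45.03 to 1029 ± 22.1 RPM (-0.76 ± 0.08). Of other small RNA machinery 4 of 11 rose and 4 fell (4 and 4; 0.231), with AGO1 up from 1137 to 2230 RPM and loqs down from 55.4 to 22.7 RPM. Of germline markers 4 of 18 rose and 3 fell (4 and 3; 0.269), with krimp up from 23.98 to 50.9 RPM. In innate immunity 2 of 6 rose and 1 fell (2 and 1; 0.943), with cact up from 57.8 to 269 RPM and dl down from 645 to 247 RPM. Blood cell markers gave 2 rises (srp and ush) and 1 fall (crq) of 5 (2 and 1; 0.897), neuron markers 2 rises (elav and futsch) of 7 (2 and 0; 0.804), and muscle markers 1 rise (Act57B) and 1 fall (sls) of 5 (1 and 1; 0.943). At the gene-table total 2 piRNA biogenesis genes rose and 5 fell, 2 germline markers rose and 6 fell, and 2 genes of other small RNA machinery rose and 5 fell. His2B:CG33868, the only tested histone gene, rose from 12.0 to 25.0 RPM (adjusted p = 0.00107).

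Between the experiments 4 lists differed at the preset and at an estimated correlation. These were JNK pathway genes (8 of 12 higher with KEE, 0 lower), heat shock and chaperone genes (8 of 11, 0 lower), translation factors (26 of 44, 2 lower) and oxidative phosphorylation genes (26 of 66, 0 lower). Their camera adjusted p was 0.00428, 0.00340, 0.00292 and 0.00644, and each had adjusted p = 0.0472 with an estimated correlation. The cytoskeleton list (14 of 21 higher, 3 lower; 0.0179), cytosolic ribosomal proteins (47 of 83, 4 lower; 0.00373) and structural RNAs (10 of 142 higher, 9 lower; 0.00292, ranked lower) differed at the preset correlation only, with adjusted p = 0.190, 0.262 and 0.262 with an estimated correlation. Among all genes 2428 of 8246 were higher with KEE and 906 lower. That excess of higher genes depended on the scaling, and the list counts for this difference were taken in RPM of the whole library only.

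Transposon piRNAs of the Daed knockdown were given as 1 merged value per group, so no test was run and the intervals below cover counting error only. The somatic gypsy-group element QUASIMODO held the most piRNAs, 47293 to 55866 RPM, a ratio of 1.18 (1.17 to 1.19) for deltaSAM over WT (95% interval). GTWIN went from 23614 to 16304 RPM (0.690 (0.684 to 0.696)) and ZAM from 14543 to 13661 RPM (0.939 (0.930 to 0.949)). Among elements of at least 20 RPM in the higher group TIRANT stood highest, from 106 to 342 RPM (3.24 (2.94 to 3.57)), followed by DM412B (2.32 (2.18 to 2.46)), DM412 from 359 to 642 RPM (1.79 (1.69 to 1.89)), S2 (1.76 (1.41 to 2.20)) and QUASIMODO2 (1.56 (1.29 to 1.89)). TOM (1.30 (1.16 to 1.45)), PROTOP (1.23 (1.06 to 1.41)), ROVER from 6575 to 8019 RPM (1.22 (1.20 to 1.24)) and IDEFIX from 6788 to 8031 RPM (1.18 (1.17 to 1.20)) were higher by less.

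Among elements of at least 20 RPM in the higher group the lowest ratios with deltaSAM belonged to DIVER (0.221 (0.159 to 0.303)) and to HELENA_RT, from 3397 to 1034 RPM (0.304 (0.295 to 0.314)). Gypsy, the retrovirus-like element that flam restrains, went from 5269 to 1961 RPM (0.372 (0.364 to 0.381)), DOC from 872 to 334 RPM (0.383 (0.363 to 0.405)) and Gypsy6A from 546 to 183 RPM (0.335 (0.311 to 0.360)). DMRT1C (0.332 (0.267 to 0.410)), G (0.346 (0.270 to 0.440)), DMRT1B (0.350 (0.289 to 0.421)), G5 (0.421 (0.309 to 0.568)) and BEL (0.421 (0.317 to 0.556)) were also low. MDG1 had a ratio of 0.658 (0.643 to 0.674), DM176 of 0.637 (0.617 to 0.657), DM297 of 0.845 (0.819 to 0.873), BLOOD of 0.891 (0.797 to 0.996) and TABOR of 0.708 (0.485 to 1.03).

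All elements together went from 204769 to 181015 RPM, 20.5% to 18.1% of the library, a ratio of 0.884 (0.882 to 0.886). Of 97 elements of at least 20 RPM, 23 were higher with deltaSAM, 5 by more than 1.5-fold, and 41 lay below by more than 1.5-fold. With the median ratio of the elements set to 1, 13 lay above and 16 below by that size. This size rule was settled after the values had been seen. LINE-like elements had a ratio of 0.493 (0.485 to 0.501), with 0 of 26 higher and 19 below by more than 1.5-fold. The gypsy group had 0.891, with 2 of 30 over and 9 under by that rule, the Copia and Pao groups 0.987, telomeric elements 0.564, DNA transposons 0.874 and elements in no list 0.998. In the Copia and Pao groups the sum was carried by ROO (45987 of 57584 reads with deltaSAM), and 0 of 11 elements lay over and 6 under by that rule, with a median ratio of 0.667. Of elements in no list 2 of 21 lay over and 5 under (median 0.853). Of DNA transposons 1 of 9 lay over and 2 under, and of telomeric elements 0 of 2 over and 2 under. The sum of elements in no list was carried by Gypsy1 (42227 of 54445 reads with deltaSAM, ratio 1.03). The fixed lists left out Gypsy1, Gypsy6A, Gypsy12A, DM412B and QUASIMODO2, among others, so the gypsy group value does not include them. DM412B (ratio 2.32) and QUASIMODO2 (1.56) were the 2 elements in no list that lay over by that rule.

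Transposon piRNAs were longer with deltaSAM. Their mean length went from 26.7 to 29.7 nt, a gain of 2.92 nt, and 124 of 129 elements with a length in both groups were longer and 3 shorter. TIRANT gained 4.45 nt, DM412 3.40 nt, QUASIMODO 3.02 nt, ZAM 2.502 nt, GTWIN 2.05 nt and HELENA_RT 1.84 nt. LINE-like elements gained 2.14 nt and the gypsy group 2.91 nt. Across the 97 elements the ratio and the gain in length had a Spearman rho of 0.46.

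**Figure D5:**
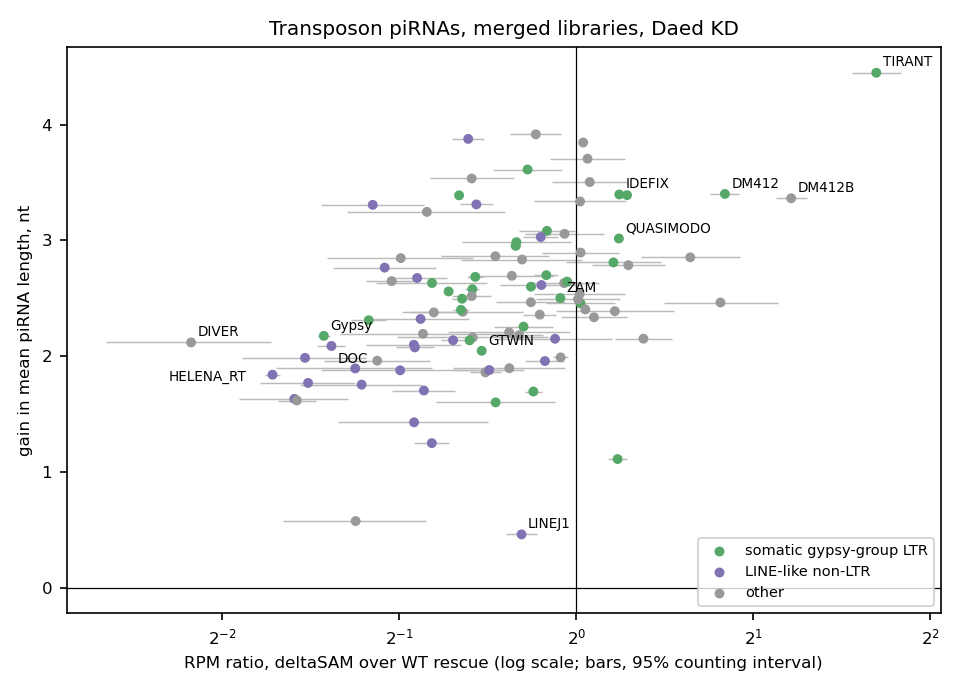
Ratio of transposon piRNAs in RPM, deltaSAM over WT, against the gain in mean piRNA length, for the 97 elements of at least 20 RPM. Lines are 95% counting intervals, and each group is 1 merged value of 3 libraries.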

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

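The count over other splits of the samples was chosen only after the result was seen. A difference between the 2 experiments brought each value here, by a test of the difference itself (limma with Benjamini-Hochberg). In total 3334 genes had a different log2 fold change with KEE than with deltaSAM. The difference was 2.98 for CNBP, 3.03 for spen, 2.40 for Bicra, 3.01 for rin and 2.77 for CG14441. It was -3.30 for CG11141, -2.37 for Tif-IA, -2.49 for CG13384, -1.97 for Uhg3 and -2.43 for ArfGAP1. For the genes named whatever the result it was 1.47 for armi, -0.84 for flam, -1.63 for tj and -1.27 for piwi. The 2 experiments differ in the protein knocked down, in the variant and in the depth of their libraries, so the source of the difference was not tested. Their WT rescues also differed. Genes took 50.2% of the library with WT in the Daed knockdown and 63.4% in the Armi knockdown. The tj share of gene reads was 1.55% and 2.04%. The WT libraries held 201 to 211 RPM of piwi in the Daed knockdown and 444 to 576 in the Armi knockdown. Reads from the rescue plasmids could not be told from endogenous armi reads.

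Of 100 drawn splits of the samples within both experiments, 2 gave as many genes as the real 3334 or more. The other one gave 3608 and kept the real groups with the labels of 1 experiment exchanged, and the next gave 1896. A split that mixes the real groups puts their difference into the spread between libraries, which lowers its count. These splits therefore cannot decide whether a chance division of these samples was the source of the count.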

How the results depend on the processing

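Scaling to the gene-table total, centring on the median gene, edgeR with TMM factors and leaving out replicate 3 of deltaSAM and of the Armi knockdown WT were tests chosen only after the result was seen; the others were planned. A turn of direction counted as a reversal only where a call was made. Of 252 results for named genes 221 kept their call or lack of one throughout. In some alternative 21 were lost, 9 were gained and 1 reversed. That was piwi with KEE, at -0.46 with DESeq2, with edgeR on DESeq2 size factors, upper quartile or TMM factors, -0.31 scaled to the gene-table total and -0.33 centred on the median gene. Its direction thus depends on the scaling. At an absolute log2 fold change of at least 1, by construction fewer genes were left, 1053 with deltaSAM and 1865 with KEE. Other alternatives kept each gene count within 1.5 times. Leaving out 1 library gave 2589 to 2934 genes with deltaSAM, 3199 to 3377 with KEE and 2951 to 3410 for the difference. Leaving out both replicates 3 gave 2999, 3583 and 3370. The correlation between experiments was 0.199 at 10 RPM, 0.213 scaled to the gene-table total and 0.204 to 0.252 with 1 library left out, and the cause was not tested. The lists that passed with deltaSAM numbered 0 at 10 RPM, 2 with a replicate block (mitochondrial ribosomal proteins, 0.0384, besides oxidative phosphorylation), 2 scaled to the gene-table total (structural and transfer RNAs besides it), 0 with an estimated correlation, 12 with fry and 1 to 4 with 1 library left out. With KEE they numbered 0 at 10 RPM, 3 with an estimated correlation and 9 to 11 with 1 library left out, against 13 in the main test. For the lists the cause was not tested. Transposons past the size rule numbered 46, against 29 with the median ratio set to 1, 23 at 100 RPM and 18 at 2-fold; the last 2 are stricter by construction, and the cause of the first was not tested. Without the 10 most abundant genes in the total, a smaller total by construction, share differences were -2.58 points for flam with KEE, 1.47 for tj with deltaSAM and -1.15 for tj with KEE. The replicate block gave 3000, 3682 and 3319 genes and 9 lists with KEE, without glycolysis (0.0624), cell cycle (0.0802), follicle cell genes (0.0837) and structural RNAs (0.0624). Deviations of libraries with the same number correlated at -0.0133 to 0.0590, so the numbers gave no hint of pairs. A lone read stood for 0.250 to 0.716 RPM, which limits calls on low genes. Not run, as the merged table holds 1 value per group, were the transposon tests, block, leave-one-out and DESeq2, and every transposon alternative of the Armi knockdown.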

Other observations

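All tests of this part but that on pooled reads were chosen only after the result was seen. More antisense and long noncoding RNA genes fell than rose in both experiments. Of 97 antisense RNA genes 2 rose and 25 fell with deltaSAM (median log2 fold change -0.44), and 5 rose and 28 fell with KEE (-0.48). Of 244 long noncoding RNA genes 13 rose and 48 fell with deltaSAM (-0.25), and 23 rose and 57 fell with KEE (-0.36). Of the 7764 genes outside the named RNA classes 1387 rose and 1475 fell with deltaSAM, and 2676 rose and 872 fell with KEE. With deltaSAM long noncoding RNA genes thus fell about as often as those genes and rose less often. Neither noncoding class was compared with genes of like abundance. In bin 3 of all genes by mean RPM, 28 of 824 rose and 123 fell with deltaSAM. In bin 5 these counts were 48 and 183 of 824. The deltaSAM counts of both classes lay near such shares, so they do not by themselves set these classes apart from low genes. With KEE 97 rose and 37 fell in bin 3, and 242 rose and 82 fell in bin 5. Of 64 snoRNA genes 12 rose and 3 fell with deltaSAM and 6 rose and 3 fell with KEE, and of 59 tRNA genes 13 rose and 4 fell and 3 rose and 3 fell. Of 12 snRNA genes 0 rose and 3 fell with deltaSAM, and 6 rose and 0 fell with KEE.

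More genes rose than fell with KEE in RPM of the whole library. Centred on the median gene or with edgeR and TMM factors, no excess of rises was left. Scaled to the gene-table total, rises made up 55% of the changed genes. That scaling shifts every gene alike, so it cannot show whether the larger part of the library assigned to genes was the source. Unbound cellular RNA in the KEE immunoprecipitates was set against structural and transfer RNAs of at least 10 RPM, whose median log2 fold change was 0.36 (-0.23 to 0.76, 20 genes) against 0.48 for all genes of that level. The 20 genes are too few, so this cannot be told apart. A first form of the test, over all 142 structural RNA genes, gave 0.04 (-0.04 to 0.11) against 0.30 and had spoken against that explanation; it was replaced after it was seen because most of these genes lie near the floor, where all genes moved less. A real gain of genic piRNAs with KEE stays open and was not tested, since RPM cannot tell it from a loss elsewhere in the library.

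With deltaSAM low-abundance genes lay lower and high-abundance genes higher. The pooled log2 ratio of recovered reads, which has no pseudocount, was 0.75 (0.61 to 0.88) higher in the highest than in the lowest of 10 bins of genes, which argues against the pseudocount as the whole cause. At 1396369 reads per library, WT libraries held 523 more genes with a read, and the lowest WT library (8962) lay above the highest deltaSAM library (8539), which argues against depth. An effect of deltaSAM on which transcripts enter piRNA production stays open as an untested hypothesis.

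Replicate 3 of WT in the Armi knockdown stood above its fellows at 6 genes by 3-fold or more and at least 20 RPM, thresholds set after the values were seen. These were lncRNA:CR44206 (798 and 707 against 3532 RPM), FBgn0263039 (517 and 486 against 2105), lncRNA:CR43651 (239 and 185 against 1267), lncRNA:CR46006 (64.3 and 53.5 against 288), lncRNA:CR43857 (44.7 and 42.0 against 212) and CG33181 (2.35 and 4.71 against 20.7). Of the 5 with coordinates 4 (80.0%, 28.4 to 99.5%) overlapped a microRNA gene, namely mir-184, mir-14, mir-276a and mir-275, against 1.51% of other genes (Fisher p = 2.8e-07), but 5 genes are too few to place that share above 50%. The median log2 ratio of 20 structural RNA genes of at least 10 RPM in that library was 0.35 (0.20 to 0.72) against a bound of 0.5, so a general excess of unbound RNA cannot be told apart either. The first form of this test, over all 142, gave 0.22 (0.13 to 0.35), below the bound, and was replaced for the same reason; no biological explanation was tested.

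The splits of 3 against 3 libraries number 10 with the real one, too few for a share under 0.05. As many genes as the real 2987 with deltaSAM came in 1 split, the real one, with 0 in the highest other. As many as the real 3684 with KEE came in 1 split, with 0 in the highest other. For lists, as many as the real 1 with deltaSAM came in 6 splits (highest other 2), and as many as the real 13 with KEE in 1 (highest other 2).

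The spread between replicates exceeded counting noise most in pairs with replicate 3 of deltaSAM (chi-square per degree of freedom 4.94 and 5.33, against 1.22 for the other pair) and with replicate 3 of WT in the Armi knockdown (5.93 and 5.73, against 1.54).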
